A study of Drosophila melanogaster with 53 samples.

How the data were processed

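Polyadenylated RNA of whole Drosophila melanogaster males was sequenced after exposure to 10, 1000, 5000, 10000 or 20000 R (roentgen, a unit of X-ray and gamma-ray exposure) or after no irradiation, per the labels. Flies were exposed 2 days after eclosion and collected 2, 10 or 20 days later. The 53 libraries fall into 18 groups of dose and day with 3 libraries each, except unirradiated controls at day 20 with 2. The labels say nothing of separate cultures or animals behind the libraries of a group, so p-values measure only the spread between these samples, which may be technical. Sample titles number the libraries of a group, but the table's columns carry no such number, so libraries are called a, b and c in column order.

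The deposited table holds a normalized signal for 15222 FlyBase genes in each library. Per the submitters' processing notes the tools were TopHat2 2.0 and DESeq with genome build dm3; the counting program and the annotation release are not given in the sources used here. It was checked that every deposited value is a whole multiple, within a tolerance of 0.1, of one step per library, so the deposited signal is a read count divided by one size factor per library. The whole reads recovered in this way sum to 15.4 to 46.2 M per library (median 23.3 M), and the deposited normalized counts to 21.5 to 30.3 M. Between 11213 and 14553 genes had a value above 0 in a library. Symbols were found for 14347 identifiers (94.3%) in a reference annotation of another genome build, so no coordinates are given, and 875 identifiers had no symbol.

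Choices made before the data were examined comprise the grouping, the tests, the gene lists, the rule for named genes and all alternatives except the last 4 named here. Values were analysed as log2(normalized count + 1), a scale that understates the change of genes with low values. Genes with a mean normalized count of at least 10 over all libraries were tested (12475). One limma fit (version 3.58.1, eBayes with trend, R 4.3.3) gave each of the 18 groups its own mean and pooled the spread over all groups, which a group of 2 libraries relies on. Contrasts were each dose against control within a day and as the mean of the 3 within-day differences, each dose against the next lower dose, days 10 and 20 against day 2 in controls, and an F test of whether a dose's response differs between days. P-values were adjusted by the Benjamini-Hochberg method per contrast, with a threshold of 0.05. Fold changes are log2 changes with standard errors (SE), and group levels are means of normalized counts with standard deviations (SD).

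In all, 29 gene lists were tested with camera in limma (preset correlation 0.01), adjusted over 435 single-day tests, 145 tests of means over days and 58 tests of age, and repeated with the correlation estimated from the data. The lists cover radiation-induced p53 target genes, DNA repair, cell death, cell cycle, germline stem cells and spermatogonia, spermatocytes and spermatids, accessory gland proteins, yolk and eggshell, antimicrobial peptides, immune recognition, Turandot and JAK/STAT genes, blood cells, heat shock proteins, glutathione S-transferases, cytochrome P450s, UDP-glucuronosyltransferases, oxidative stress, cytoplasmic and mitochondrial ribosomal proteins, proteasome, oxidative phosphorylation, digestive enzymes, muscle, phototransduction, neurons, cuticle, lipid storage, insulin and clock. Members were also counted as adjusted over the list alone; 35 list symbols matched no gene in the table. Testis, accessory gland and blood cell lists are also markers of single tissues within a whole fly.

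Named genes were taken by rule from genes past the threshold with a mean of at least 50 normalized counts. The rule took the 10 largest rises and 10 largest falls per mean dose contrast and per age contrast, 3 and 3 per single-day contrast, and 5 and 5 per dose step. To these it added the 4 members per list with the smallest p at 20000 R over days and a fixed set of radiation genes (p53, rpr, hid, skl, egr, Xrp1, Corp, Ku80, Irbp, mre11, Gadd45, RnrL). Of that set, rpr and skl were not among the genes tested. The text gives part of the genes so taken. Mst87F, aly, Ubi-p63E, osk, Cp36, Yp3, dj and lncRNA:roX1 lie outside the rule; each was chosen after its values were seen.

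Overlaps of called genes were set against the product of both counts over the genes tested, and against 40 simulations of unchanged groups. Each simulated library, controls included, took each gene's mean over all libraries plus the residuals of a library drawn at random from all. Doses of the same day shared their simulated controls. The pipeline was tested on simulated data: of 100 genes raised or lowered by 1 on the log2 scale, limma recovered 63% in a contrast over days and 33% within day 10, and of 100 changed by 2 it recovered 85% and 71%, with 5 and 6 false calls. In the same test edgeR recovered 63% and 84% over days with 6 false calls, and DESeq2 66% and 86% with 21. Camera called 2 of 2 changed lists and 0 of 20 unchanged ones. In these simulated data each gene varied independently, without the structure that genes of the real libraries share. The false calls therefore do not show how the tests behave under such structure.

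Other settings fixed beforehand were a pseudocount of 0.25 or 8, no filter, a mean of at least 100, median-of-ratios rescaling, quantile normalization, robust eBayes, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 (Wald test) on the recovered reads, only the libraries of that day, a change of at least 1 on the log2 scale, and leaving out each library in turn. The last 4 alternatives were chosen after seeing the data: without the 6 libraries with the fewest genes above 0 (at most 12229), without 9 libraries (those 6 and 3 with over 10000 normalized counts of Yp1 or of summed His1 histone genes), with 2 residual components as covariates, and with a replicate block by column order (the place of a library in its group as an additive term). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for the remaining steps. Raw reads were not analysed here, since only the deposited table was used.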

Results

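Expression of 15222 genes was measured by RNA sequencing in 53 libraries of whole adult males. Unirradiated controls and flies given 10, 1000, 5000, 10000 or 20000 R were each sampled 2, 10 and 20 days after exposure. There were 3 libraries per dose and day, and 2 for controls at day 20. Recovered depth ran from 15.4 to 46.2 M reads per library. By the study's title, the question is whether the response to radiation sets in above a threshold dose.

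A few libraries stood apart from others of their group. At most 12229 genes had a value above 0 in 6 libraries: control day 20 b, 10 R day 2 b and c, 10 R day 10 c, 10 R day 20 c and 5000 R day 20 c. Yp1, which encodes a yolk protein made by females, stood at 89258 normalized counts in 10 R day 10 a and at 116245 in 10000 R day 10 c. The His1 histone genes summed to 90346 in 20000 R day 10 a. Counts of called genes are given below with all 53 libraries and, where they move by more than 1.5 times, without these 9.

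At 10000 R and 20000 R, transcripts of the male germ line fell at days 10 and 20. Mst98Ca, a transcript of spermatids that encodes a sperm tail protein, stood at 17226 ± 649 normalized counts in day 10 controls (SD, n = 3). It stood at 312 ± 79.4 after 10000 R and at 137 ± 31.7 after 20000 R (SD, n = 3 each). Those falls were -5.82 ± 0.21 and -6.99 ± 0.21 on the log2 scale (SE; adjusted p = 3.73e-24 and 7.39e-27). S-Lap8, a leucylaminopeptidase of sperm, fell by 7.07 at 20000 R on day 10 and by 7.56 on day 20. Prosbeta5R1, a testis-specific proteasome subunit, dropped from 1306 ± 139 to 13.9 ± 11.6 normalized counts at 20000 R on day 10 (SD, n = 3). Hsp60B, a chaperone needed for making sperm, fell by 6.74 ± 0.24 (SE), and RpS19b, a ribosomal protein paralog of germ cells, by 5.97 ± 0.57. At day 2 the same transcripts were near control: Mst98Ca stood at 21810 ± 3019 after 20000 R against 20535 ± 1635 (SD, n = 3 each), a change of 0.08 ± 0.21 (SE) that missed the threshold.

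The spermatocyte and spermatid list moved nearly as a whole. Of its 49 measured members, 49 fell at 10000 R on day 10 and 43 at 20000 R (47 adjusted over the list alone). On day 20, 42 and 43 of them fell (45 at 20000 R adjusted over the list alone). Median changes were -5.74 and -6.31 at day 10 and -5.46 and -6.88 at day 20. As the mean over days at 20000 R, 46 members fell (48 adjusted over the list alone) with a median of -4.42 (camera adjusted p = 5.32e-40; adjusted p = 0.00259 with an estimated correlation). At 10000 R the count was 47 and the median -3.75. The germline stem cell and spermatogonia list had 4 of 12 members lower at 20000 R (4 adjusted over the list alone) and a median of -0.97, and missed the threshold as a list (adjusted p = 0.277). Its member bgcn, a partner of the differentiation factor bam, fell by 3.78 ± 0.31 over days (SE), and bam itself by 2.33 ± 0.60. Under quantile normalization that list's median was -0.04, and without the 9 libraries it was -2.03 with 8 members lower and 2 higher.

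**Figure D1:**
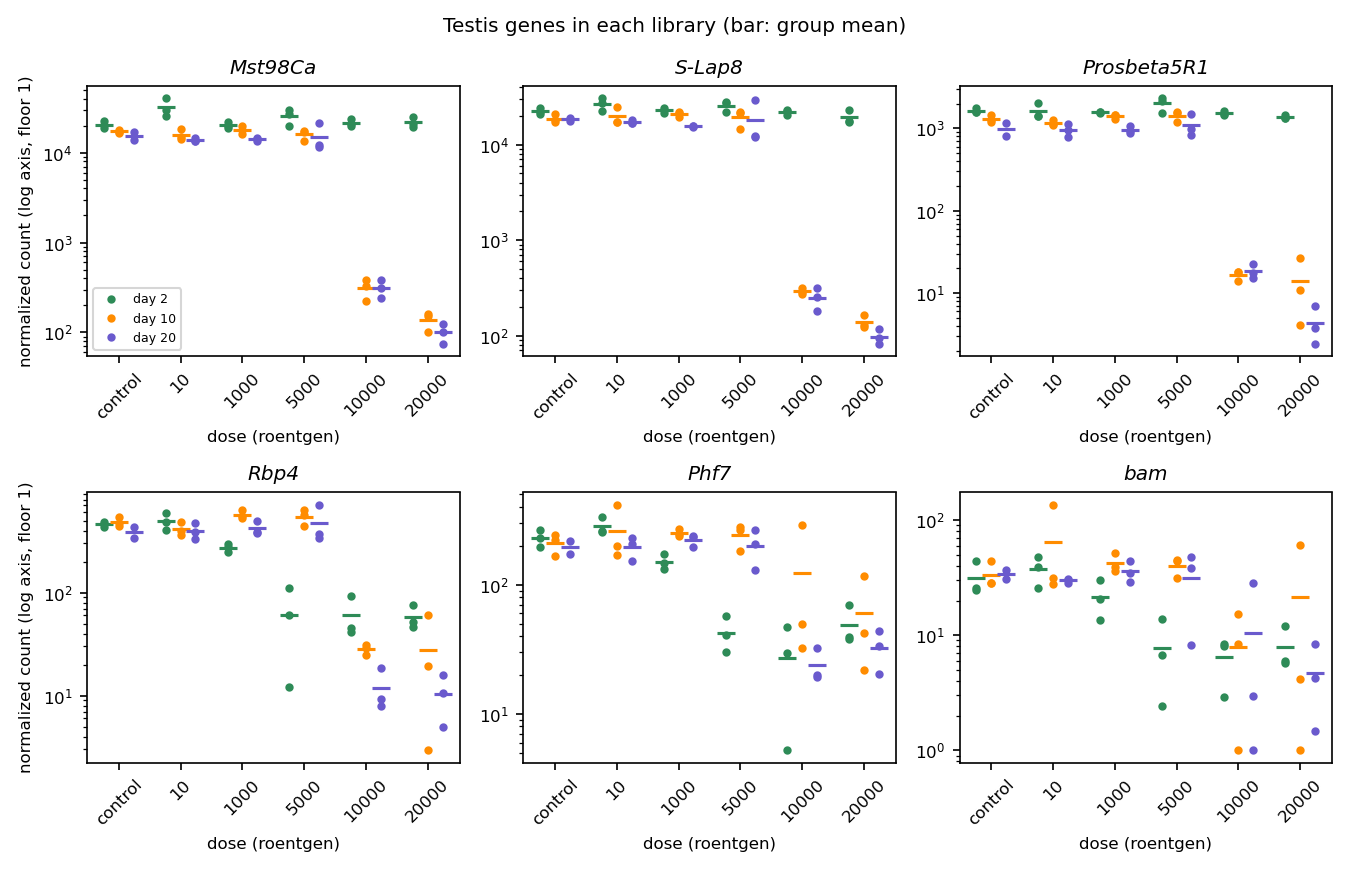
Normalized counts (log axis, floor 1) of 6 testis genes by dose and day; points are libraries and bars group means. Mst98Ca, S-Lap8 and Prosbeta5R1 are low at days 10 and 20 after 10000 R and 20000 R, whereas Rbp4 and Phf7 are also low at day 2 from 5000 R upwards.

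Members of other lists fell too, among them testis-specific proteasome subunits. Whether the other falls given here lie in testis transcripts was not tested. In the proteasome list, 18 of 42 members fell at 20000 R over days (22 adjusted over the list alone; median -0.26, adjusted p = 0.00324), led by the testis-specific subunits Prosbeta5R1 and Prosalpha6T. That call was lost with an adjusted p = 0.59 with an estimated correlation. Hsc70-2 (-3.12 ± 0.13, SE), Hsp27 (-3.05 ± 0.30) and Hsp68 (-1.56 ± 0.13) were among 9 of 24 heat shock proteins that fell, while 2 rose; median (0.06) and mean (-0.54) of that list differ in sign, and it missed the threshold (adjusted p = 0.231). In the cell cycle list, 15 of 41 genes fell (16 adjusted over the list alone; median -0.46, 0.05 under quantile normalization; adjusted p = 0.0719), among them polo, a mitotic kinase, by 3.81 ± 0.43 (SE). DNA repair genes went both ways, with 3 of 38 higher and 6 lower (adjusted p = 0.732). The photolyase phr6-4 (-1.94 ± 0.20) and the helicase Blm (-1.20 ± 0.15) were among those that fell. Of 44 oxidative phosphorylation genes, 2 fell, among them ND-51L1 by 3.77 ± 0.35 (median 0.02, mean -0.13, adjusted p = 0.582). In mitochondrial ribosomal proteins 4 of 69 fell (1 adjusted over the list alone; adjusted p = 0.731), with mRpL15 at -0.51 ± 0.12 (SE). The signalling ligand upd1 fell by 3.08 ± 0.45 among Turandot and JAK/STAT genes, of which 3 of 14 rose, including Tep3 by 0.65 ± 0.21 (adjusted p = 0.334 for the list).

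In counts of genes, 2755 passed the threshold at 10000 R on day 10 (276 higher, 2479 lower) and 2667 at 20000 R (339 higher, 2328 lower). On day 20 the counts were 2633 (554 higher, 2079 lower) and 2806 (698 higher, 2108 lower). Over days they were 3451 (801 higher, 2650 lower) and 3549 (963 higher, 2586 lower). Rises moved with single libraries more than falls did. Those of day 20 numbered 69 and 92 without control day 20 b and 1266 and 1420 without control day 20 a. They were 331 and 344 without 10000 R day 20 b or c, and 408 and 437 without 20000 R day 20 b or c. Rises of day 10 numbered 144 to 166 at 10000 R and 195 to 208 at 20000 R without any one control of that day, 174 and 141 without 10000 R day 10 b or c, and 214 without 20000 R day 10 a. Over days 628 were left at 20000 R without control day 20 b. Without the 9 libraries 809 rose at each of the doses on day 10, 388 and 436 on day 20, and 1642 and 1623 over days. By edgeR 553 and 592 rose on day 10 and 295 and 400 on day 20, and by DESeq2 418 and 602 on day 10. Without a filter 962 rose at 20000 R on day 10 (29.1% of calls), and 509 with only the libraries of that day. Falls stayed within 1.5 times in each of these settings. The split by direction depends on scaling, since a fall of so many abundant transcripts changes what the remaining share is set against. Quantile normalization moved the median log2 change of all genes from 0.03 to 0.43 at 10000 R and from 0.10 to 0.40 at 20000 R on day 10. On day 20 it moved it from 0.07 to 0.32 and from 0.06 to 0.33. The share of calls that were higher went from 10.0% to 63.9% and from 12.7% to 63.1% on day 10, and from 21.04% to 50.4% and from 24.9% to 53.7% on day 20. Over days the share went from 23.2% to 65.5% at 10000 R and from 27.1% to 66.5% at 20000 R. Rises named below therefore hold relative to the deposited scaling.

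**Figure D2:**
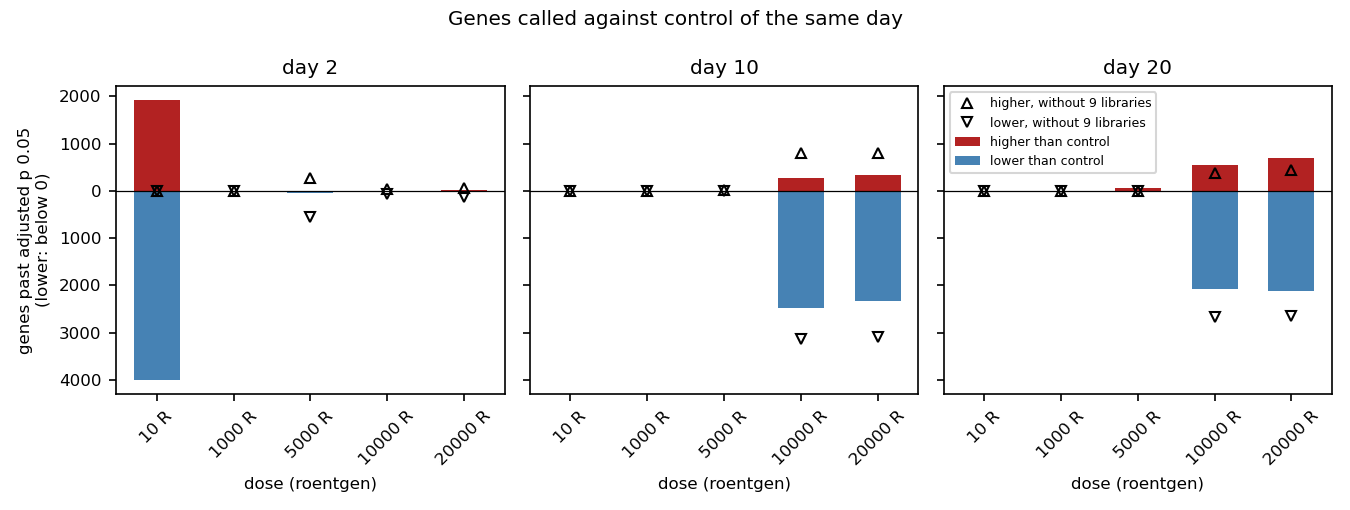
Genes past the threshold against control (y axis, number of genes, higher and lower) for each dose (R) and day; triangles give the counts without the 9 libraries. Counts lie between 2633 and 2806 at 10000 R and 20000 R on days 10 and 20, and at 5921 at 10 R on day 2, where 1 gene was left without the 9 libraries.

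Radiation-induced p53 target genes rose together at 20000 R. Irbp, the fly Ku70 that binds broken DNA ends, rose by 1.26 ± 0.20 over days (SE; adjusted p = 1.56e-06), from 234 ± 18.8 to 621 ± 24.7 normalized counts at day 10 (SD, n = 3 each). Gadd45, a stress gene, rose by 0.95 ± 0.12, mre11, a nuclease subunit of break repair, by 0.78 ± 0.15, and egr, the fly tumour necrosis factor, by 0.60 ± 0.11. RnrL, the large subunit of ribonucleotide reductase, rose by 1.80 ± 0.51, and Corp, a p53 target, by 0.81 ± 0.19. Xrp1, a transcription factor of the radiation response, rose by 0.35 ± 0.07. Of 11 measured members, 9 rose (10 adjusted over the list alone), with a median of 0.78 (camera adjusted p = 0.000228; adjusted p = 0.00295 with an estimated correlation). At 10000 R 8 rose with a median of 0.55 (adjusted p = 0.00324; adjusted p = 0.0235 with an estimated correlation). Ku80, the partner of Irbp, missed the threshold over all libraries (1.14 ± 0.53, SE, adjusted p = 0.105) and passed it without the 9 libraries (1.15, adjusted p = 8.6e-12). At day 10 Ku80 stood at 787 ± 73.9 after 20000 R against 306 ± 51.1 (SD, n = 3 each). The rises of p53 (0.50 ± 0.16) and of the death gene hid (0.60 ± 0.19) ended without those libraries, at 0.28 (adjusted p = 0.112) and 0.41 (adjusted p = 0.0909).

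The p53 list passed at each day at 20000 R, with medians of 0.36 at day 2, 0.94 at day 10 and 1.15 at day 20. These calls held with an estimated correlation (adjusted p = 0.0017, 0.017 and 0.017). At 10000 R the median was 0.49 at day 10 (adjusted p = 0.083 with an estimated correlation) and 0.83 at day 20 (adjusted p = 0.048 with an estimated correlation). At 5000 R it was 0.39 at day 20 (camera adjusted p = 0.0087; adjusted p = 0.064 with an estimated correlation). At 1000 R over days it was 0.17 (camera adjusted p = 0.034; adjusted p = 0.16 with an estimated correlation). The cell death list, made of caspases and their regulators, had a median of 0.17 at 20000 R and missed the threshold (adjusted p = 0.302). The inhibitor Diap2 was at -0.19 ± 0.08 there (SE, not past the threshold) and fell by 0.25 ± 0.08 at 10000 R.

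**Figure D3:**
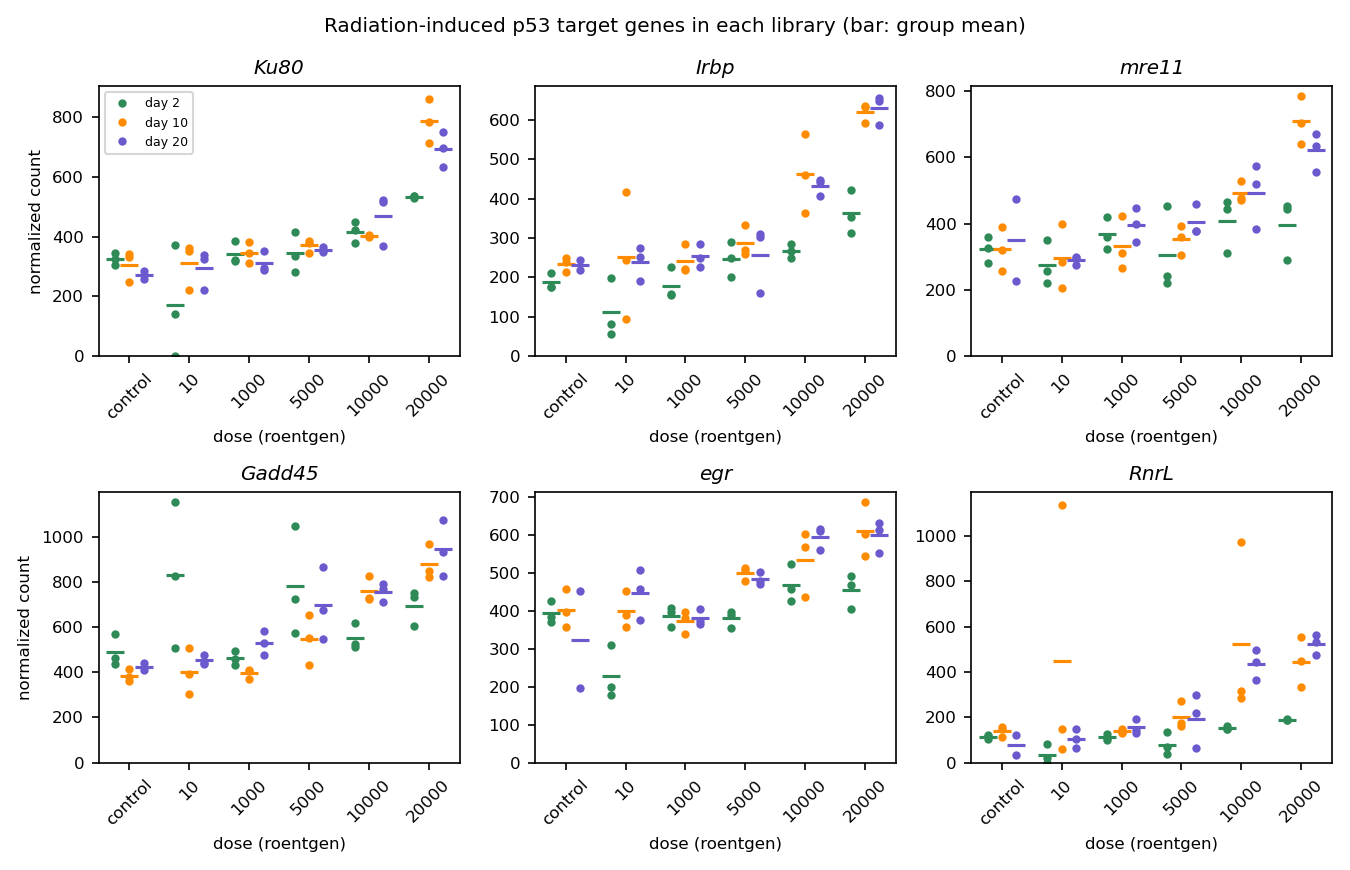
Normalized counts of 6 p53 target genes by dose and day; points are libraries and bars group means. Irbp rises from 234 in day 10 controls to 621 after 20000 R, and Ku80 from 306 to 787.

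Transcripts of tim and Nfs1 also rose at the high doses, while lists of detoxification genes gave no call that held with an estimated correlation. Those of tim, a core clock gene, rose by 0.68 ± 0.06 at 10000 R and by 0.79 ± 0.06 at 20000 R over days (SE; adjusted p = 7.67e-12 and 1.06e-13), with changes of 0.72, 0.82 and 0.84 at the 3 days at 20000 R. Of 10 clock genes, 4 rose at 20000 R, per, vri and Pdp1 being the others (median 0.23, adjusted p = 0.023; adjusted p = 0.122 with an estimated correlation). At day 2 the clock list passed with an estimated correlation too at 20000 R (median 0.29, adjusted p = 0.0007) and at 10000 R (median 0.16, adjusted p = 0.029). Nfs1, a cysteine desulfurase that supplies sulfur for iron-sulfur clusters, rose by 0.90 ± 0.08 at 10000 R and by 1.26 ± 0.08 at 20000 R (adjusted p = 2.55e-16). GstD2, a glutathione S-transferase, rose by 3.29 ± 0.80 at 20000 R on day 10, and GstD1 by 0.43 ± 0.11 over days, while GstS1 fell by 1.03 ± 0.10. In that list 4 of 33 rose and 2 fell (adjusted p = 0.0796). Cytochrome P450s had 6 of 79 higher, with Cyp304a1 at 1.64 ± 0.42 and Cyp6d2 at 1.11 ± 0.31, and 1 lower (median 0.35, adjusted p = 0.00449; adjusted p = 0.881 with an estimated correlation). UDP-glucuronosyltransferases had 2 of 28 higher, among them Ugt49C1 at 0.85 ± 0.16 (median 0.71, adjusted p = 0.0324; adjusted p = 0.881 with an estimated correlation).

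Blood cell genes had 3 of 15 higher at 20000 R, with the engulfment receptor NimC2 at 0.77 ± 0.20 (SE) and the peroxidasin Pxn at 0.39 ± 0.13 (median 0.39, adjusted p = 0.0212; adjusted p = 0.285 with an estimated correlation). Muscle genes had 3 of 25 higher, with the tropomyosin Tm1 at 0.33 ± 0.10 (median 0.26, adjusted p = 0.0328; adjusted p = 0.881 with an estimated correlation). Cuticle proteins split, with 14 of 58 higher and 6 lower (median 0.31, adjusted p = 0.0395; adjusted p = 0.59 with an estimated correlation); Cpr76Bd rose by 1.25 ± 0.18 and Twdlalpha fell by 2.76 ± 0.21. Ribosomal proteins had 7 of 81 higher and 5 lower, the falling ones including RpS19b and RpS10a, both testis paralogs (median 0.17, adjusted p = 0.0101; adjusted p = 0.881 with an estimated correlation, and 0.65 under quantile normalization). Neuronal genes had 2 of 28 lower, the monoamine transporter Vmat (-0.45 ± 0.06) and the dynamin shi (-0.25 ± 0.06), and missed the threshold as a list (adjusted p = 0.41). Digestive enzymes (adjusted p = 0.311) had 1 of 51 higher and 4 lower, among them the protease Jon65Ai at -0.80 ± 0.18. Oxidative stress genes had 2 of 27 higher and 2 lower, the peroxiredoxin Prx4 falling by 1.04 ± 0.13 (adjusted p = 0.327). Lipid storage (median 0.23, adjusted p = 0.0691), insulin signalling (0.22, adjusted p = 0.134), phototransduction (0.05, adjusted p = 0.306) and immune recognition (0.18, adjusted p = 0.097) missed the threshold. Antimicrobial peptides had a median of -0.64 over days, with a camera direction upwards (adjusted p = 0.913). Of the lists called over days, 4 of 43 calls held with an estimated correlation, all of spermatocyte and p53 target genes, and 11 of 112 single-day calls did.

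At day 2 few genes passed at the high doses. Transcripts of kek3, a transmembrane protein of the Kekkon family, rose from 315 ± 35.3 in controls to 893 ± 149 after 5000 R, 1383 ± 90.7 after 10000 R and 1646 ± 136 after 20000 R (SD, n = 3 each). The log2 rises were 1.49, 2.14 and 2.39 (each ± 0.22, SE; adjusted p = 0.00026, 8.43e-08 and 3.74e-09). CCHa1, a gut and brain peptide hormone, rose from 50.9 ± 1.92 to 207 ± 20.2 after 10000 R and to 568 ± 57.5 after 20000 R (SD, n = 3 each), by 2.00 ± 0.36 and 3.45 ± 0.36. The first of these CCHa1 calls ended without control day 2 b (1.97, adjusted p = 0.0529). The vesicular transporter prt rose by 2.43 ± 0.49 at 20000 R. At day 10 kek3 stood at 336 ± 101 after 20000 R against 349 ± 61.5. For both kek3 and CCHa1 the response differed between days at 20000 R (F test, adjusted p = 2.2e-08 and 1.43e-06).

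Some genes of the male germ line and of immunity fell at day 2. Rbp4, an RNA-binding protein of spermatocytes, stood at 461 ± 28.11 normalized counts in controls, 273 ± 23.4 after 1000 R, 61.2 ± 49.2 after 5000 R, 59.9 ± 28.8 after 10000 R and 57.8 ± 15.3 after 20000 R (SD, n = 3 each). It fell by 3.36 ± 0.57 at 5000 R (SE, adjusted p = 0.00235), and by 3.02 and 3.00 at the next doses. Phf7, a chromatin reader of the male germ line, fell by 2.43 ± 0.57 at 5000 R and by 3.45 ± 0.57 at 10000 R, and aub, a Piwi protein, by 3.61 ± 0.84 at 5000 R. The inducible chaperone Hsp68 fell by 1.00, 1.11 and 1.12 (each ± 0.22, SE). At 20000 R the immune peptide gene BomBc1 fell by 4.18 ± 0.73 and stood at 121 ± 31.1 against 2175 ± 353. In unirradiated controls BomBc1 was also among the 10 largest falls taken by rule from day 2 to day 10. At 5000 R Dro, an antimicrobial peptide, fell by 6.24 ± 1.47 and the serine protease homolog SPH93 by 8.31 ± 1.61. Falls called at 5000 R numbered 50 over all libraries, but 4 without control day 2 a and 3 without control day 2 c. These are fewer than the falls named here for 5000 R, so some of those calls ended. The antimicrobial peptide list had medians of -1.64, -1.61, -1.85 and -2.64 from 1000 R to 20000 R. Each was called by camera, and each call was lost (adjusted p = 0.06, 0.91, 0.35 and 0.21 with an estimated correlation). These medians share the same day 2 controls, so they are not independent of one another.

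In counts, 56 genes passed at day 2 at 5000 R (6 higher, 50 lower), 12 at 10000 R (3 higher, 9 lower) and 20 at 20000 R (10 higher, 10 lower). Without the 9 libraries, none of which belongs to these groups, a smaller pooled spread gave 820, 108 and 194. The count at 5000 R ran from 4 without control day 2 c to 995 without 5000 R day 2 a, and that at 10000 R from 3 without control day 2 b to 8. Falls called at 10000 R numbered 1 without control day 2 b and 1 without 10000 R day 2 b. In either case the falls of Rbp4 and Phf7 there did not both hold. At 20000 R edgeR called 20 genes and DESeq2 44.

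**Figure D4:**
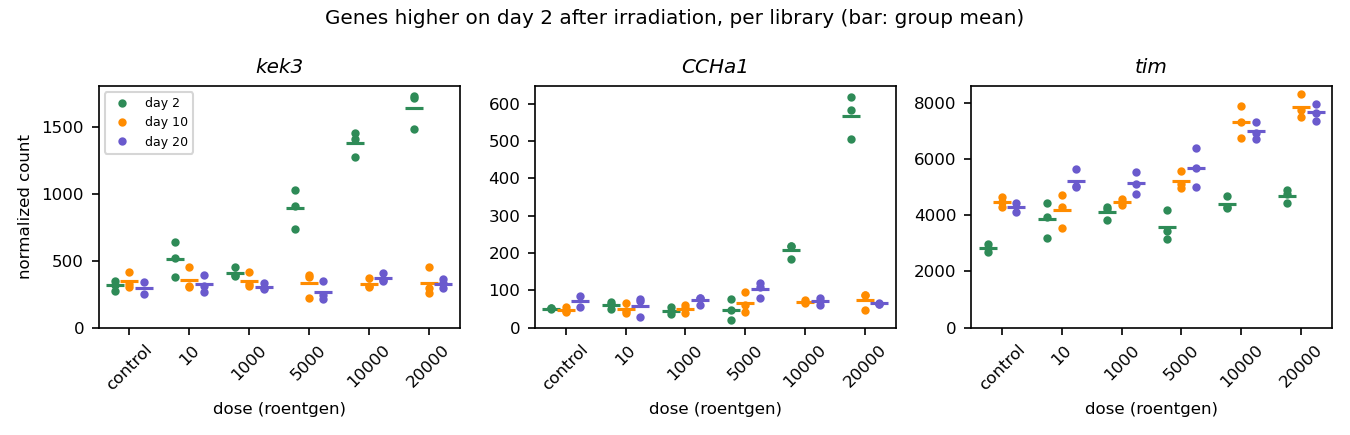
Normalized counts of kek3, CCHa1 and tim by dose and day; points are libraries and bars group means. The highest group means are at day 2 after 20000 R for kek3 (1646) and CCHa1 (568), and at day 10 after 20000 R for tim (7858).

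At 5000 R, between the low and the high doses, the testis transcripts Mst98Ca and Rbp4 were near control levels on day 10. Mst98Ca stood at 16015 ± 2097 and Rbp4 at 545 ± 94.4 against 17226 ± 649 and 484 ± 49.4 in controls (SD, n = 3 each), with log2 changes of -0.11 ± 0.21 and 0.16 ± 0.57 (SE). Mst87F, another testis gene, stood lower in each library of 5000 R on day 10 than in each control of that day. Its normalized counts were 4812, 5781 and 5768 against 6684, 7375 and 7758. Over days the spermatocyte list had a median of -0.02 (adjusted p = 0.913). Nfs1 rose by 0.56 ± 0.08 over days, and Nfs1 and CG5773 were the 2 genes called at day 10 (0.74 ± 0.14 and 1.14 ± 0.20, SE; adjusted p = 0.0216 each). Without 5000 R day 10 a 156 genes passed there, 6 without c, and 0 by limma without b or without any one control of day 10, where edgeR called 0 and DESeq2 5 over all libraries. Gadd45 rose by 0.60 ± 0.12 and tim by 0.32 ± 0.06 over days. Falls over days included the ligand jeb (-1.08 ± 0.28), the transcription factor scrt (-1.06 ± 0.27), the potassium channel Sh (-1.03 ± 0.22) and lncRNA:noe (-1.54 ± 0.39); each of these calls ended without the 9 libraries (-0.91, -0.91, -0.84 and -1.25). Neuronal genes had a median of -0.26 with 3 of 28 lower (1 higher and 7 lower adjusted over the list alone; adjusted p = 8.42e-05; adjusted p = 0.59 with an estimated correlation). Cytoplasmic ribosomal proteins had 11 of 81 higher (37 adjusted over the list alone; median 0.30, adjusted p = 8.84e-17; adjusted p = 0.115 with an estimated correlation). Over days 568 genes passed (171 higher, 397 lower), between 65 without control day 20 b and 1359 without 5000 R day 2 a, and 285 without the 9 libraries. These calls follow libraries b and c of 5000 R: leaving out any one a library raised the count (1359, 1000 and 1141 at days 2, 10 and 20), and leaving out any one b or c lowered it to between 224 and 306. By edgeR 139 were higher and 145 lower (48.9% higher against 30.1%), and by DESeq2 345 and 420 (45.1%). Of 59 genes called at day 20 (54 higher, 5 lower), 0 were called by limma without the 9 libraries, where 400 had an unadjusted p under 0.05, and edgeR called 0 and DESeq2 28 over all libraries.

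At 1000 R few differences passed the test. Neither Mst98Ca (-0.03 ± 0.12), nor Gadd45 (0.09 ± 0.12), nor Irbp (0.03 ± 0.20, SE) passed over days, and tim was at 0.27 ± 0.06. Over days limma called 0 genes (242 with an unadjusted p under 0.05), edgeR 0 and DESeq2 1, and without control day 20 a limma called 210. At day 2 limma called 0 (48 with an unadjusted p under 0.05), edgeR 0 and DESeq2 3, and without 1000 R day 2 b limma called 1. At day 10 limma called 0 (37 with an unadjusted p under 0.05), edgeR 0 and DESeq2 0. The proteasome list was called over days at a median of -0.05 (adjusted p = 0.0008; adjusted p = 0.5 with an estimated correlation). The clock list at day 2 had a median of 0.09 and held with an estimated correlation (adjusted p = 0.0017). At day 20 snsl and CG8299 were the 2 genes called; without control day 20 b the count was 0, and without control day 20 a it was 761.

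At 10 R the many calls at day 2 rested on a pair of libraries, b and c. BomS2, an immune peptide gene, had a log2 change of -7.02 ± 1.98 (SE) over all 3 libraries and of 0.16 without the 9 libraries. The metallothionein MtnC (-6.42 ± 1.68) and the cytochrome P450 Cyp4e1 (-6.45 ± 1.77) were among the falls. Ubi-p63E, a polyubiquitin gene, stood at 148500 ± 248536 against 355984 ± 11728 normalized counts (SD, n = 3 each). Srg3 rose by 2.32 ± 0.28, and that call ended without the 9 libraries (1.39). Cytochrome P450s, glutathione S-transferases and UDP-glucuronosyltransferases had medians of -2.04, -2.78 and -3.08, lost with an estimated correlation (adjusted p = 0.91, 0.91 and 0.95) and at -0.10, -0.02 and -0.16 without the 9 libraries. In total 5921 genes passed at day 2 (1925 higher, 3996 lower), 1266 without 10 R day 2 b, 7867 without 10 R day 2 a, and 1 without the 9 libraries, which leaves a single 10 R library that is assumed to vary like the other groups. Quantile normalization moved the share of higher calls from 32.5% to 52.6% and the median of all genes from -0.26 to 0.17. The direction also turned with the tool: edgeR called 2321 higher and 1104 lower (67.8% higher), and DESeq2 2107 and 1592 (57.0%).

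At 10 R on day 10 limma called 0 genes (406 with an unadjusted p under 0.05), edgeR 1 and DESeq2 14. The yolk and eggshell list had a median of 2.82 there (camera adjusted p = 7.6e-18; adjusted p = 0.19 with an estimated correlation) and of -0.74 without the 9 libraries, one of which holds 89258 counts of Yp1. On day 20 snsl and l(2)37Cd passed, 0 genes without control day 20 b and 646 without control day 20 a. Over days 1690 genes passed at 10 R (466 higher, 1224 lower), 5901 without 10 R day 2 a, and 0 by limma without the 9 libraries. The count was 1 without any one of control day 2 b or c, control day 10 b or c, 10 R day 2 b or c, 10 R day 10 c and 10 R day 20 c. The share of higher calls was 27.6%, and 46.3% under quantile normalization. Over all libraries it turned to 93.9% with edgeR (338 higher, 22 lower) and to 81.7% with DESeq2 (549 higher, 123 lower).

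From dose to dose, the largest step in the testis genes lay between 5000 R and 10000 R. S-Lap8 fell by 4.10 ± 0.12 over days (SE, adjusted p = 1.61e-26), CG1631 by 4.99 ± 0.30, CG12853 by 4.87 ± 0.27 and the tetraspanin Tsp33B by 4.90 ± 0.38. Yp1 rose by 3.15 ± 0.91 and the mitotic phosphatase stg by 2.01 ± 0.57, with the Yp1 library of 10000 R day 10 in this contrast. In this step 4761 genes passed (1814 higher, 2947 lower; 38.1% higher, and 67.0% under quantile normalization). From 10000 R to 20000 R, S-Lap8 fell again by 0.86 ± 0.12, Adgf-E, an adenosine deaminase-related growth factor, by 1.51 ± 0.23 and CG14931 by 1.80 ± 0.42, and Nfs1 rose by 0.36 ± 0.08. This step held 188 genes (41 higher, 147 lower), 355 without 20000 R day 10 a and 714 without the 9 libraries. From 1000 R to 5000 R, Achl fell by 1.40 ± 0.15 (adjusted p = 5.27e-07) and the mannosidase LManVI by 1.07 ± 0.21, and CG5773 (0.72 ± 0.12) and Gadd45 (0.51 ± 0.12) rose. Here 795 genes passed (222 higher, 573 lower), between 287 without 5000 R day 2 c and 1636 without 5000 R day 2 a, and 1859 without the 9 libraries. By edgeR 231 were higher and 240 lower (49.04% higher against 27.9%), and by DESeq2 491 higher and 625 lower. From 10 R to 1000 R 3436 genes passed (2640 higher, 796 lower; 76.8% higher, and 52.98% under quantile normalization), 6598 without 10 R day 2 a, and 0 by limma without 10 R day 2 b, 10 R day 10 c or 10 R day 20 c or without the 9 libraries. Its direction turned with the tool: edgeR called 133 higher and 897 lower (12.9% higher) and DESeq2 317 higher and 886 lower over all libraries. MtnC at 3.89 ± 0.97 and Cyp4e1 at 3.79 ± 1.02 were among its largest rises, at 0.31 and 0.07 without the 9 libraries.

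**Figure D5:**
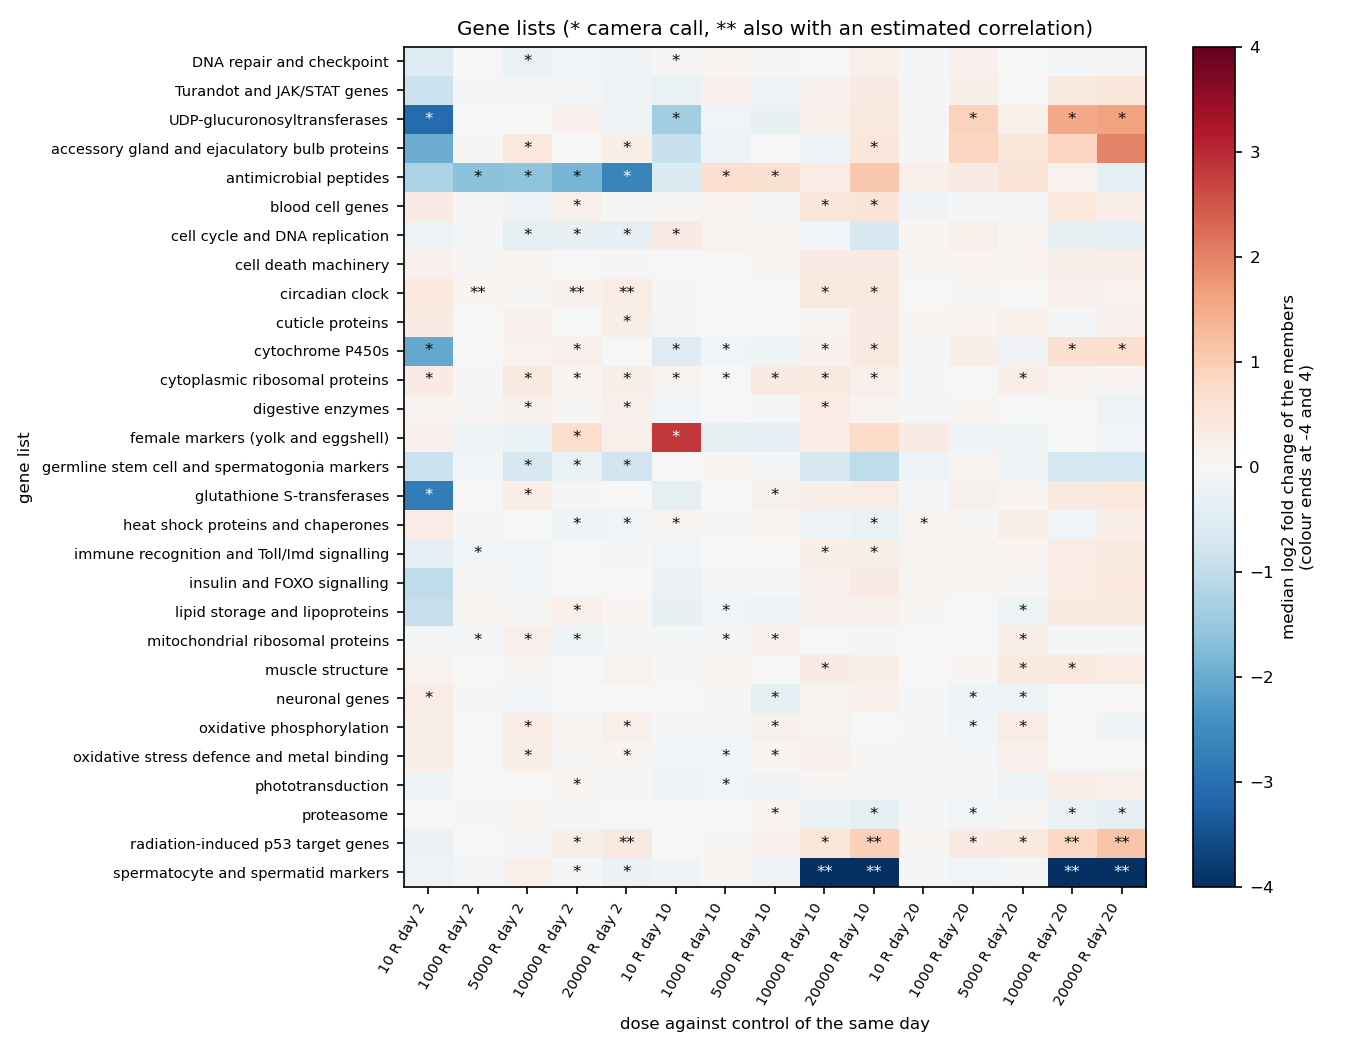
Median log2 change of 29 gene lists (one line each) against control for each dose and day; colours end at ±4, one star marks a camera call and 2 stars a call that also held with an estimated correlation. The spermatocyte and spermatid list has medians from -5.46 to -6.88 after 10000 R and 20000 R at days 10 and 20.

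With age, muscle genes fell in unirradiated males at both later days. Act88F, the actin of flight muscle, stood at 7883 ± 531 at day 2, 782 ± 64.1 at day 10 (SD, n = 3 each) and 898 ± 212 at day 20 (SD, n = 2), and fell by 3.33 ± 0.25 and 3.15 ± 0.28 (SE). Of 25 muscle genes 16 fell at day 10 (19 adjusted over the list alone; median -1.29) and 16 at day 20 (18 adjusted over the list alone; median -1.48), and both calls held with an estimated correlation (adjusted p = 0.000619 and 0.019). Of 44 oxidative phosphorylation genes 17 and 18 fell (30 each adjusted over the list alone; medians -0.76 and -0.82), among them cype, a cytochrome c oxidase subunit; the call at day 20 was lost (adjusted p = 0.086 with an estimated correlation). Lsp2, a larval serum storage protein, rose by 3.21 ± 0.32 and 3.60 ± 0.36, the lipase Lip3 by 3.60 ± 0.93 and 5.09 ± 1.04, and the amylase relative Amyrel by 3.15 ± 0.43 and 3.60 ± 0.48. Digestive enzymes as a list had 6 of 51 higher and 2 lower at day 10 and 8 higher and 5 lower at day 20 (medians 0.13 and 0.33; adjusted p = 0.31 and 0.369 with an estimated correlation). The lipid storage list was called at both days (medians 0.43 and 0.29; adjusted p = 0.0254 and 0.162 with an estimated correlation). Clock genes were higher at both (medians 0.29 and 0.49; adjusted p = 0.00102 and 0.00109 with an estimated correlation), with tim up by 0.65 ± 0.11 and 0.59 ± 0.12. Of 81 cytoplasmic ribosomal proteins 29 rose at day 20 (46 adjusted over the list alone; median 0.60). NimC4, an engulfment receptor, fell by 4.44 ± 0.66 and 3.29 ± 0.74, and the cuticle gene Acp1 by 4.13 ± 0.75 and 5.43 ± 0.84. In total 344 genes passed at day 10 (217 higher, 127 lower), 892 without the 9 libraries, and 1021 at day 20 (487 higher, 534 lower), 311 without control day 20 b and 2169 without control day 20 a. At day 20 quantile normalization moved the share of higher calls from 47.7% to 66.2% and the median of all genes from -0.22 to 0.05, and edgeR gave a share of 79.8% (746 higher, 189 lower).

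The falls after the high doses were shared between days and between doses. At 20000 R, 1944 genes fell at both day 10 and day 20 (393 by chance) and 123 rose at both (18.97 by chance), with a correlation across genes of 0.91 and a covariance of 3.84. At 10000 R, 1939 genes fell at both days (413 by chance) and 59 rose at both (12.3 by chance), with 0.87 and 3.21. Between 10000 R and 20000 R, 2183 genes fell at both doses on day 10 (463 by chance) and 1962 on day 20 (351 by chance). Rises shared by both doses numbered 110 (7.50 by chance) and 468 (30.997 by chance), and rises of each dose at day 20 dropped to 69 and 92 without control day 20 b. In 40 simulations of unchanged groups with shared simulated controls, the median number of calls shared in either direction was 0 on both days. The highest was 0 at day 10 and 1386 at day 20. That highest value counts rises and falls together, against 468 rises and 1962 falls shared in the data at day 20. The simulated controls were drawn from all libraries, those that stood apart included. The simulations therefore do not decide how many of the 468 shared rises the real controls can bring. Correlations across genes between the doses were 0.94 at day 10 and 0.98 at day 20. Simulated ones had a median of 0.56 at day 10 (-0.067 to 0.96, a range that holds the observed value) and of 0.53 at day 20 (-0.10 to 0.92). Covariances of 3.46 and 4.13 stood against simulated medians of 0.15 and 0.15 and highest values of 0.93 and 1.31. Genes are not independent replicates, and the 3 or 2 controls of a day were not split between both doses, so part of the excess may come from shared controls. Whether the response differed between days was tested by interaction. At 10000 R 1756 genes and at 20000 R 1717 genes passed this test, and 504 did at 10 R, 7 at 5000 R and 0 at 1000 R (limma; 201 with an unadjusted p under 0.05, edgeR 0, DESeq2 1). Without 10 R day 2 b the count at 10 R was 0 and without 10 R day 2 a 5628. Without control day 20 a the counts at 1000 R and 5000 R were 301 and 453.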

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

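The tests of explanations in this part were chosen after the result was seen, as was the step added to the splits for interactions; the splits of the libraries were fixed beforehand. Responses that differ between days, by an F test of the interaction in limma, drew attention here: 1756 genes at 10000 R (40 of them named genes), 1717 at 20000 R (42 named), 504 at 10 R (2 named) and 7 at 5000 R (2 named). At 10000 R and 20000 R they include S-Lap8, Mst98Ca and Prosbeta5R1, near control at day 2 and far below it at days 10 and 20. Transcripts of kek3 and CCHa1 ran the other way, high at day 2 and near control at day 10.

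Other splits of the same libraries were counted for each result. Over days, at 10000 R as many genes were called in 1 of 100 splits (3451, highest other 2663). At 20000 R this was so in 1 of 100 too (3549, highest other 2318). That is the lowest share that 100 splits allow. Labels of single libraries were exchanged. Chance is thus excluded as the whole source of these counts only if libraries of a group are independent samples, which the labels do not state. The same holds for the steps from 1000 R to 5000 R (795 in 1 of 100, highest other 1), 5000 R to 10000 R (4761 in 1 of 100, highest other 3714) and 10000 R to 20000 R (188 in 1 of 100, highest other 168). The count of 795 follows libraries b and c of 5000 R, however. It rose to 1636, 1267 and 1406 without the a library of day 2, 10 or 20. Without any one b or c it fell to between 287 and 551. Splits of labels do not tell such a structure from dose. From 10 R to 1000 R the share was small too (3436 in 2 of 100), but the split with the highest count, 5156, set 5 libraries of 10 R, 4 of them with few genes detected, with 4 of 1000 R against the rest. That step gave 0 genes by limma without the 9 libraries, so its count follows a few libraries and is not put down to dose. Chance was not excluded over days at 10 R (1690 in 9 of 100, highest other 4236), 1000 R (0 in 100 of 100, highest other 0) and 5000 R (568 in 5 of 100, highest other 1411). The split with 1411 set the a libraries of 5000 R on all 3 days with 6 control libraries, and a replicate block by column order gave 793 for the real one.

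For interactions, a dose's mean difference over days was taken out before labels were exchanged, since exchanged labels would turn it into an interaction. The shares were then 1 of 100 at 10000 R (1756, highest other 1604) and 1 of 100 at 20000 R (1717, highest other 1615). If libraries of a group are independent, chance is excluded as the whole source of these counts. The highest others differ from the real grouping or its mirror by 1 library and lie close to it. Splits as fixed beforehand, with the mean difference left in, did not exclude chance. They gave 1756 in 6 of 100 (highest other 2958) and 1717 in 7 of 100 (highest other 2475). The exclusion therefore also rests on a step chosen after those counts were seen. Chance was also not excluded, with that step, at 10 R (504 in 23 of 100, highest other 5052), 1000 R (0 in 100 of 100, highest other 0) and 5000 R (7 in 13 of 100, highest other 597). Splits that call several times the real count, as at 10 R and 5000 R, point to a structure of the samples.

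Within a day, 10 splits are too few for a share under 0.05. At day 2 the real counts and highest others were 5921 and 5936 at 10 R (2 of 10 as large), 0 and 0 at 1000 R (10 of 10), 56 and 1 at 5000 R (1 of 10), 12 and 0 at 10000 R (1 of 10), and 20 and 0 at 20000 R (1 of 10). At day 10 they were 0 and 0 at 10 R (10 of 10), 0 and 0 at 1000 R (10 of 10), 2 and 0 at 5000 R (1 of 10), 2755 and 5 at 10000 R (1 of 10), and 2667 and 480 at 20000 R (1 of 10). Control day 10 against day 2 gave 344 and 0 (1 of 10).

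The first pattern weighed is the 5921 genes called at 10 R on day 2. A response shared by the 3 irradiated libraries is argued against by 10 R day 2 a, in which the 3996 genes called lower had a median log2 shift of -0.033, against -4.73 in b and -2.28 in c. A shortage of many transcripts in b and c, also seen in unirradiated control day 20 b, remains open as a candidate source: 80.6% of these genes were lower in control day 20 b than in a, against 59.1% of all tested genes. Why libraries b and c lack these transcripts was not tested.

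The second pattern is Yp1, at 89258 normalized counts in 10 R day 10 a and 116245 in 10000 R day 10 c. In 10 R day 10 a, 22 of 22 yolk and eggshell genes were higher than in each of 51 other libraries, which is consistent with RNA of females in that library. In 10000 R day 10 c, RNA of females with late egg chambers is argued against, since 19 eggshell genes stood at a median of 0.293% of the level that the ratio of Yp1 (1.30) would bring, and 6 of the 22 genes exceeded the 51 other libraries. A response to 10000 R of that size, shared by the libraries of that dose and day, is argued against too. The others had Yp1 at 329 and 508, at most 0.437% of its level in c. Both lie above the highest control library (201), so a smaller shared rise is not argued against. RNA of females without late egg chambers stays open and had no test of its own: osk, a gene of the ovary, stood at 1668 normalized counts in 10 R day 10 a and at 1178 in 10000 R day 10 c, where the eggshell gene Cp36 stood at 12205 and 0, and Yp3 at 57268 and 46271.

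The third pattern is the rise of p53 target genes at 20000 R. A smaller share of testis RNA would raise all other transcripts alike. The list's median of 0.78 lay at percentile 99.95 of 10000 random sets of 11 genes from 170 markers of other tissues (upper end of the middle 95%: 0.34). That argues against such an equal rise as the whole cause. The random sets mix genes of several tissues, so the percentile does not address how far genes of a single tissue move together. The accessory gland list, which was among those pooled, had a median no lower at 20000 R over days. The 9 libraries that stood apart are argued against by an adjusted p of 2.11e-05 without them, and the deposited scaling by an adjusted p of 0.00185 under quantile normalization. What stays open as a hypothesis is that irradiated males carry raised p53 target expression up to 20 days after 20000 R, which was found and tested on the same data, and p53 activity itself was not measured.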

How the results depend on the processing

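Alternatives without the 6 low-detection libraries, without the 9 libraries that stood apart with 2 residual components as covariates and with a replicate block by column order were chosen after seeing the data; all others were fixed beforehand. The counts at 10000 R and 20000 R on days 10 and 20, and their means over days, stayed within 1.5 times of the reported values under every setting fixed beforehand except quantile normalization and a minimum change of 1 on the log2 scale, and without the 6 or 9 libraries. Median-of-ratios rescaling moved no count by more than 1.5 times. Most small counts, at 5000 R and below and at day 2, moved with the libraries and the tool, and except where fewer libraries or genes were tested the cause was not tested. Small changes are what the number of libraries limits most: on simulated data 33% of changes of 1 on the log2 scale were recovered within a day.

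With edgeR, day 2 counts were 3425 (10 R), 10 (5000 R) and 7 (10000 R), day 10 counts 1 (10 R) and 0 (5000 R), and day 20 counts 0, 0 and 0 (10 R, 1000 R, 5000 R). Over days edgeR called 360 at 10 R and 284 at 5000 R, 1030 from 10 R to 1000 R and 471 from 1000 R to 5000 R, with 1 and 4 interaction genes at 10 R and 5000 R. With DESeq2, day 2 counts were 3699 (10 R), 3 (1000 R), 22 (10000 R) and 44 (20000 R), day 10 counts 14 (10 R) and 5 (5000 R), and day 20 counts 1, 1 and 28 (10 R, 1000 R, 5000 R). Over days DESeq2 called 672 at 10 R, 1 at 1000 R and 1203 from 10 R to 1000 R, with 176, 1 and 16 interaction genes at 10 R, 1000 R and 5000 R.

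Without the 6 low-detection libraries, day 2 counts were 0, 3, 450, 34 and 55 from 10 R to 20000 R, 12 at 5000 R on day 10 and 0, 0 and 0 at 10 R, 1000 R and 5000 R on day 20. Means over days were 0 at 10 R and 152 at 5000 R, steps 0 from 10 R to 1000 R, 1459 to 5000 R and 370 from 10000 R to 20000 R, control day 10 gave 780, and interactions 0 at 10 R and 4 at 5000 R. Without the 9 libraries, day 2 counts were 1, 4, 820, 108 and 194, 22 at 5000 R on day 10 and 0, 0 and 0 at the same 3 doses on day 20. Means were 0 and 285, steps 0, 1859 and 714, control day 10 gave 892, and the 10 R interaction 0. Where these leave 1 library in a group (10 R day 2, control day 20 and 10 R day 10), it is assumed to vary like the other groups.

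Under quantile normalization, day 2 counts were 3, 152, 26 and 48 from 1000 R to 20000 R, day 10 counts 5957 and 5819 at 10000 R and 20000 R, and day 20 counts 0, 0, 0 and 4246 at 10 R, 1000 R, 5000 R and 20000 R. Means were 6679 and 6933 at 10000 R and 20000 R, the step from 5000 R to 10000 R 7254, the 10 R interaction 2, and genes shared between days 3127 at 10000 R and 3484 at 20000 R, and between these doses at day 10 4754. With a minimum change of 1, 10 R gave 3472 at day 2, 5000 R gave 1 at day 10, means were 899, 47, 2023 and 2149 (10 R, 5000 R, 10000 R, 20000 R), steps 1731, 18, 2066 and 71 in order of dose, and control ageing 153 and 544.

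The 2 residual components lie across the groups and only narrow the spread. With them, day 2 counts were 3, 541, 35 and 83 from 1000 R to 20000 R, day 10 counts 872 (10 R) and 5 (5000 R), and day 20 counts 88, 316, 413, 4573 and 4827 from 10 R to 20000 R. Means were 5552, 2, 1993, 5363 and 5462, steps 6189, 2306 and 387 (all but 5000 R to 10000 R), ageing 728 and 3570, interactions 5352, 2, 11, 3074 and 3204, and genes shared by both high doses at day 20 4114.

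The replicate block by number that was named beforehand was not run, because the table's columns carry no replicate number. Column order is not arbitrary, however: in 18 of 18 groups library a had the lowest score on the first component of the residuals (51.6% of their variance) and the highest level of dj, a testis gene. Residuals of libraries in the same place correlated with a median of 0.18 (-0.61 to 0.84, 61.1% of 442 pairs over 0.1), with 0.39 among a, 0.035 among b and 0.11 among c, against -0.084 for different places. By their mean correlation 35 of 53 libraries were closest to their own place, a hint from the data and not from the design. As some pairs lie below 0.1, places were not taken as paired, and the reported tests leave this structure in the spread. The replicate block by column order gave 107 genes at 5000 R on day 2, 0 at 1000 R on day 20 (919 with an unadjusted p under 0.05), 1236 from 1000 R to 5000 R and 1719 for the 10 R interaction. All 31 other counts and overlaps stayed within 1.5 times, and 159 of 160 gene results kept direction and side of the threshold; Diap2 at 20000 R passed it (-0.20).

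Without a filter, counts were 28 at 5000 R on day 2, 0 and 38 at 1000 R and 5000 R on day 20, and 106 for the 10 R interaction. With a mean of at least 100, day 20 counts were 1, 0 and 14 from 10 R to 5000 R and the 5000 R interaction 3. A pseudocount of 8 gave 22 and 34 at 10000 R and 20000 R on day 2, 1, 0 and 19 from 10 R to 5000 R on day 20 and 9 for the 10 R interaction. A pseudocount of 0.25 gave 4, 20 and 92 from 10 R to 5000 R on day 20 and 4 for the 5000 R interaction. Robust eBayes gave 0 at 1000 R on day 20. Only the libraries of that day gave 1 and 3 at 1000 R and 5000 R on day 2, 0 at 5000 R on day 10 and 0, 0 and 0 from 10 R to 5000 R on day 20. List calls that held with an estimated correlation were 11 of 112 within days, 4 of 43 over days and 7 of 25 with age; without the 9 libraries 88, 35 and 22 held, and under quantile normalization 88, 27 and 22.

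Leaving out 1 library at a time gave, at day 2, counts of 1266 to 7867, 0 to 1, 4 to 995, 3 to 8 and 14 to 17 from 10 R to 20000 R. At day 10 they were 0 to 0, 0 to 0, 0 to 156, 2396 to 2571 and 2290 to 2694, and at day 20 0 to 646, 0 to 761, 0 to 846, 1967 to 3175 and 2013 to 3374. Means gave 1 to 5901, 0 to 210, 65 to 1359, 3134 to 3511 and 3224 to 3761, steps 0 to 6598, 287 to 1636, 4405 to 5084 and 159 to 355, ageing 251 to 268 and 311 to 2169, and interactions 0 to 5628, 0 to 301, 0 to 453, 1574 to 2410 and 1546 to 2353. Genes shared between days were 1738 to 1987 at 10000 R and 1833 to 2100 at 20000 R, and between these doses 2014 to 2440 at day 10 and 1821 to 2958 at day 20. At day 20 the high end of each dose came without control day 20 a, and at 5000 R on day 10 without 5000 R day 10 a.

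Of 160 gene results, 160 kept direction and side of the threshold under robust eBayes and under median-of-ratios rescaling, 158 without a filter, 156 and 154 with pseudocounts of 0.25 and 8, 154 under quantile normalization and 137 with edgeR; 139 of 152 did with DESeq2, 133 of 160 with a minimum change of 1, and 16 of 29 single-day results with only the libraries of that day, where 13 missed the threshold. Without the 6 libraries 129 did, without the 9 libraries 132, and 2072 of 2266 when 1 library was left out. BomS2 at 10 R on day 2 reversed to 0.16 without the 6 and without the 9 libraries, and CG32276 from 10 R to 1000 R reversed to -0.054 and -0.027; in both cases 2 low libraries of 10 R day 2 were left out.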

Other observations

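All tests of explanations in this part were chosen after the result was seen. Some transcripts of the mitochondrial genome and of seminal fluid proteins were higher at 20000 R. Over days mt:CoI, a cytochrome c oxidase subunit, rose by 3.09 ± 0.47 from 10000 R to 20000 R (SE, adjusted p = 3.66e-05) and by 3.08 ± 0.49 against control. Levels varied widely between libraries, with 98252 ± 87957 normalized counts at day 10 after 20000 R against 7509 ± 2215 in controls (SD, n = 3 each). mt:Cyt-b (3.07 ± 0.61), mt:CoII (3.06 ± 0.76), mt:CoIII (2.88 ± 0.50) and mt:ATPase6 (3.83 ± 0.91) rose as well against control over days (SE). Single-day calls of mt:Cyt-b at day 10 and mt:ATPase6 at day 20 ended without the 9 libraries (2.68 and 1.82). Sfp60F, a seminal fluid protein, rose by 3.21 ± 0.53 from 10000 R to 20000 R, and Acp54A1 by 2.79 ± 0.61 and Acp95EF by 3.08 ± 0.71 against control. Of 25 accessory gland proteins 4 rose at 20000 R over days (4 adjusted over the list alone; median 0.79, adjusted p = 0.0212; adjusted p = 0.829 with an estimated correlation).

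Among cuticle genes, Acp65Aa rose by 3.15 ± 0.52 over days at 20000 R (SE) and stood at 67.4 ± 6.74 normalized counts at day 10 against 3.30 ± 1.22 (SD, n = 3 each). Fer3HCH, a mitochondrial ferritin, fell by 2.76 ± 0.68, and Cpr56F by 2.87 ± 0.45. At day 20 the digestive protease Jon65Ai fell by 2.23 ± 0.33 at 20000 R, from 2297 ± 108 (SD, n = 2) to 491 ± 73.3 (SD, n = 3). The yolk and eggshell list had 1 of 21 members higher at 20000 R over days (median 0.31, adjusted p = 0.275). lncRNA:roX1, a male dosage compensation RNA, fell by 0.80 ± 0.19 over days at 5000 R (SE, adjusted p = 0.0139). This fall lies in libraries b and c of each day (3235 to 6868 normalized counts), whereas the a libraries of 5000 R stood at 9553, 9654 and 9911, within the range of the controls (8649 to 11930).

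A hypothesis was tested that early germ cells are lost within 2 days from 5000 R upwards, return at 5000 R and stay lost at higher doses. At day 2 the mean log2 level of 12 stem cell and spermatogonia genes differed by -0.52 between the 9 libraries of 5000 R and above and the 9 of lower doses (2-sided permutation test with 100000 permutations, p = 0.0637), which leaves early loss undecided over all libraries. Of the 9 lower-dose libraries 2 are the low-detection libraries of 10 R. Without them the difference was -0.84 (9 against 7, exact permutation test over 11440 splits, p = 0.000175), and the highest of the higher doses (6.607) lay just above the lowest of the others (6.606). This goes with early loss, though it rests on leaving out 2 libraries after their values were seen. Both permutation tests exchanged single libraries and not whole dose groups. Their p-values therefore treat libraries of a group as independent, which the labels do not state. By day 10 the level at 5000 R lay -0.065 from control, which is consistent with a return. At 10000 R and 20000 R together it lay -1.23 from control at day 10 (-2.02 at 10000 R without library c and -2.39 at 20000 R without library a), which is consistent with a loss that lasts. Cell numbers were not measured, so a change of expression within germ cells may give the same values.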
